A study of Heterocephalus glaber with 6 samples.

How the data were processed

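Epidermis of naked mole-rats was separated with dispase at 5 mg/ml overnight, and RNA with an integrity number above 7 was depleted of ribosomal RNA and made into strand-directional libraries, per the labels' protocols. The deposited tables hold raw counts per gene ID, per the labels, and the values are whole numbers that sum to a different total in each library. Cutadapt, FastQC, Bowtie2 and TopHat2 are named without role or version, per the submitters' processing notes. The genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. Reads of overlapping or antisense loci, of near-identical copies, and of several assembled loci that are pieces of 1 gene may therefore be split or shared in ways that cannot be checked.

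The 8 count columns belong to 6 GEO samples. Each DMBA and DMBA/TPA sample has 1 column, and each of the 2 control samples has 2 columns, whose names number them as separate acetone controls. Each column was taken as 1 library, a rule written before the data were examined. The column of the second DMBA/TPA sample is headed by a number alone and was assigned through its file. Libraries of a group were checked for duplication by a chi-square test over loci with a pair count of at least 20. The statistic per degree of freedom was 41.2, 26.2, 137.4 and 34.8 in the DMBA controls, DMBA/TPA controls, DMBA and DMBA/TPA, so none of the pairs agreed within sampling noise. No row lacked a gene ID, and 9626 of the 33281 loci had no count in any library.

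Gene symbols were not assigned. The files pair no ID with a symbol, and in the table of RefSeq genes used here, of assembly H.glaber_assembly_v1.0, 0 of 42221 rows carry an Ensembl ID and 0 of the count tables' IDs matched. For this reason none of the 54 gene lists, with 1128 symbols, that had been fixed before the data were examined could be tested, and the planned set tests with camera and fry were not run. The rule fixed for named genes required a symbol and was the up to 10 higher and 10 lower loci of largest log2 fold change per treatment comparison. It could not be applied. In its place, and chosen after seeing that no symbols could be matched, the locus of smallest p in each direction of each treatment comparison is shown, among loci with a mean of at least 2 log2 CPM and groups whose CPM did not overlap.

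Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, which left 18422 loci, 4465 with Ensembl-format and 13957 with assembled IDs. Libraries were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted over all 4 groups, with 4 residual degrees of freedom and a biological coefficient of variation of 25.7%. In all, 5 contrasts were tested: each treatment against its own controls, the difference between those effects, the controls against each other, and the treated groups against each other. P-values were adjusted by the Benjamini-Hochberg method, and loci with an adjusted p below 0.05 were called. Standard errors were the log2 fold change divided by the square root of the F statistic. For loci with no counts in a group, medians of log2 fold changes were also computed with the fold taken against a floor of 3 counts per library. Log2 CPM used a prior count of 2. Mean CPM values are after TMM scaling. Shares of counts and total counts were compared by exact two-sided permutation tests over the 36 splits that exchange libraries only between a treatment and its own controls, and overlaps by Fisher's exact test. The sets of the 10 and the 20 most abundant loci were chosen after the data were examined.

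The procedure was tested on simulated counts over 18422 loci with the real library sizes. The means were those of the acetone libraries in every group, and the spread was the one edgeR had fitted. Changed loci were drawn from those above a minimum expected count. For the DMBA/TPA comparison it called 0 of 67 loci changed by 1.5-fold, 15 of 67 changed by 2-fold and 53 of 66 changed by 4-fold, with 5 of 18222 unchanged loci called. So few changed loci make the adjusted threshold strict. In the deposited data 3042 of the 4886 loci called in DMBA/TPA were past 2-fold, so smaller changes were called there too, and the recovered shares do not carry over to comparisons with many changed loci. For the DMBA comparison, simulated with no change, 0 of 18422 loci were called. Because the simulated spread was the fitted one, this does not test whether the fit describes the spread between the real libraries.

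The alternatives chosen before the data were examined were DESeq2 1.42.0, upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 2 libraries, fits of the compared groups alone, pooled control sets, summed control columns, a block for sample number in the treated groups, a threshold of 0.1 for the overlap, and leaving out each library. Where a library is left out its group holds 1, which is assumed to vary like the other groups. Total-count scaling, removal of the 20 most abundant loci, thinning of each library to the smallest total, exchanged control sets, and pooled control sets for the difference of effects were added after seeing the data. Figures were drawn with matplotlib 3.10.9.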

Results

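RNA was sequenced from the epidermis of naked mole-rats, long-lived subterranean rodents, after skin treatment with the carcinogen DMBA, a polycyclic aromatic hydrocarbon used as a tumour initiator, or with DMBA and TPA, a phorbol ester used as a tumour promoter. The animals were 6 to 7 months old. DMBA was applied at 1 mg/ml in a volume of 100 µl, and in the DMBA/TPA group TPA at 0.1 mg/ml followed 2 times per week. The DMBA group was harvested on day 10 and the DMBA/TPA group on day 46. Each treatment had its own acetone-treated controls, whose day of harvest is not given in the sources used here. There were 4 groups of 2 libraries each, 8 libraries in all. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these libraries, which may be technical.

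The total counts were 22852358 and 27486387 in the DMBA controls, 24337164 and 24153238 in the DMBA/TPA controls, 30080934 and 35238753 in the DMBA libraries, and 34537133 and 38124702 in the DMBA/TPA libraries. The 4 treated libraries were thus all deeper than the 4 acetone libraries (exact two-sided permutation test within the 2 treatment sets, p = 0.0556, the smallest its 36 splits allow, so the design cannot reach 0.05). Counts were given for 33281 gene IDs, called loci here, of which 16308 had the format of Ensembl gene IDs and 16973 that of loci from a transcript assembly. The Ensembl-format IDs made up 49% of the loci and held 3.47% of the counts. No locus could be given a gene symbol, so results are described by locus class, abundance and direction, with 4 loci shown by ID. These were picked among loci with a mean of at least 2 log2 CPM and groups whose CPM did not overlap, named eligible here. After low-count filtering 18422 loci were tested, and a locus is called when its adjusted p in edgeR's quasi-likelihood test is below 0.05.

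The libraries of a group resembled each other more than those of other groups. Across loci, the correlation of log2 CPM, read counts scaled to library size, lay between 0.9535 and 0.9674 for the 4 pairs of libraries within a group, and between 0.9115 and 0.9519 for the 24 pairs between groups. Loci are not independent replicates, so these correlations carry no p-value. The first principal component held 33.4% of the variance, with the DMBA/TPA libraries at one end and their controls at the other. The second held 17.8% and set the DMBA libraries below the other libraries.

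**Figure D1:**
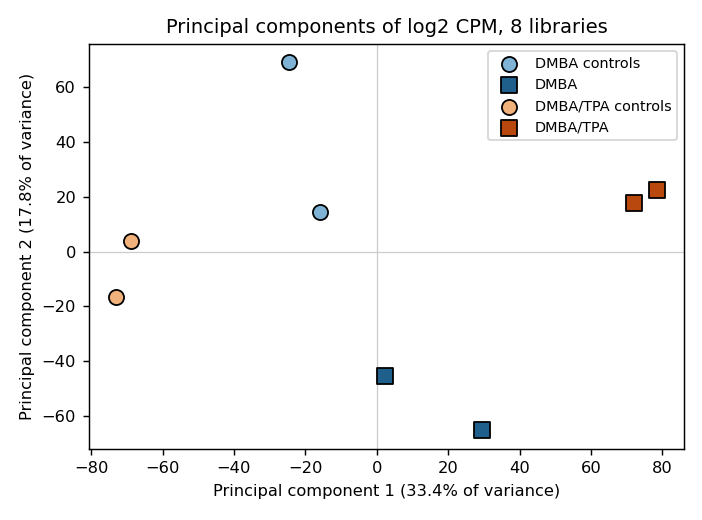
Scores of the 8 libraries on the first (x axis) and second (y axis) principal component of log2 CPM over 18422 loci, with the share of variance on each axis. Circles are acetone controls and squares treated libraries; the DMBA/TPA libraries score 72.1 and 78.6 on the first component and their controls -73.1 and -69.0.

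The comparison of DMBA with its controls asked which transcripts differed in the epidermis on day 10 after the carcinogen. Of 204 called loci, 154 rose and 50 fell after DMBA. The majority rested on 1 library, since without the second DMBA library 408 loci were called higher and 615 lower. The called loci had a median absolute log2 fold change of 1.51, and 179 were past 2-fold. With so few loci called the adjusted threshold is strict and passes mainly large changes. These sizes therefore do not measure how strong the DMBA effect was. In 15 of the called loci a group had no counts; with these at their bound against a floor of 3 counts per library the median was 1.51 as well. MSTRG.2456 had the smallest p among the eligible loci that rose. It went from 43.6 ± 4.28 CPM (SD, n = 2) in the controls to 709.6 ± 215 CPM (SD, n = 2) after DMBA. Its log2 fold change was 4.03 with a standard error of 0.286 (edgeR adjusted p = 0.00189). ENSHGLG00000009109 had the smallest p among the eligible loci that fell, from 73.1 ± 14.4 to 20.6 ± 1.14 CPM (SD, n = 2 each). Its log2 fold change was -1.83 with a standard error of 0.184 (edgeR adjusted p = 0.00642). None of the 20 most abundant loci was called.

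In this comparison the Ensembl-format and the assembled loci were called at rates of 0.963% and 1.15% (Fisher's exact test across loci, p = 0.324). The count of calls in DMBA was fragile: it was 7 without the first DMBA control library, 53 without either DMBA/TPA control library, 26 or 29 without the first or the second DMBA/TPA library, 342 without the first DMBA library and 1023 without the second. It was 946 with DESeq2, 469 with no low-count filter, 16 with only its own 2 groups in the fit, 1046 against the DMBA/TPA controls, and 0 when the 2 control columns were summed into 1 library (edgeR, 1786 loci at an unadjusted p below 0.05), which also ended the calls of MSTRG.2456 and ENSHGLG00000009109 (edgeR adjusted p = 0.121 for both).

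The comparison of DMBA/TPA with its controls asked the same on day 46, after repeated TPA. Of the tested loci 26.5% were called, 4886 in all, of which 2668 rose and 2218 fell. The median absolute log2 fold change of the called loci was 1.15, also with the 108 that had no counts in a group at their bound, and 1509 rose and 1533 fell by more than 2-fold. Loci of every abundance class were called, from 4.29% of the loci under 0 log2 CPM to 36% of those between 3 and 6 and 37.4% of those above 6. Among the assembled loci 29.9% were called, against 15.9% of the Ensembl-format loci (Fisher's exact test across loci, p = 6.74e-82). The Ensembl-format loci were also less abundant, with a median of 1.20 log2 CPM against 3.63.

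MSTRG.14369 had the smallest p among the eligible loci that rose. It went from 1.91 ± 0.136 CPM in the DMBA/TPA controls to 183.9 ± 68.1 CPM after DMBA/TPA (SD, n = 2 each). Its log2 fold change was 6.59 with a standard error of 0.353 (edgeR adjusted p = 0.000136). The low value was in the DMBA/TPA controls alone, since this locus stood at 81.3 ± 13.9 CPM in the DMBA controls and at 124.6 ± 30.7 CPM after DMBA (SD, n = 2 each). With both control sets pooled its log2 fold change was 2.14 and it was no longer called (edgeR adjusted p = 0.34, the highest of its 19 alternatives, of which the lowest was 6.41e-90 with DESeq2). Against the DMBA controls its log2 fold change was 1.18 and it was called (edgeR adjusted p = 0.0238). MSTRG.1947 had the smallest p among the eligible loci that fell, from 33.5 ± 1.07 to 2.57 ± 0.514 CPM (SD, n = 2 each). Its log2 fold change was -3.71 with a standard error of 0.237 (edgeR adjusted p = 0.000353). It was also higher in the DMBA/TPA controls than in the DMBA controls, which had 13.6 ± 2.26 CPM (SD, n = 2), with a log2 difference of 1.30 (edgeR adjusted p = 0.0368). This control difference was no longer called without any 1 of the control or DMBA/TPA libraries. The lowest adjusted p of its 16 alternatives came from DESeq2 (DESeq2 adjusted p = 4.2e-05).

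The split between rises and falls in DMBA/TPA depended on how the libraries were scaled. With TMM scaling 54.6% of the called loci were higher, with upper-quartile scaling 40.3%, and with total counts alone 16.7%, where the median log2 fold change of all loci was -0.52. In all 4 settings, these scalings in edgeR and DESeq2 with its own scaling and test, 1035 loci were called higher and 2195 lower. The DMBA split moved from 75.5% to 57.0% higher with total counts, and 80 loci were called higher and 49 lower in all 4 settings. The count of DMBA/TPA calls was 1337 or 2090 without the first or the second of its control libraries, 1954 or 1536 without the first or the second DMBA/TPA library, 7338 with only its own 2 groups in the fit, 891 with the control columns summed and 2454 against the DMBA controls.

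**Figure D2:**
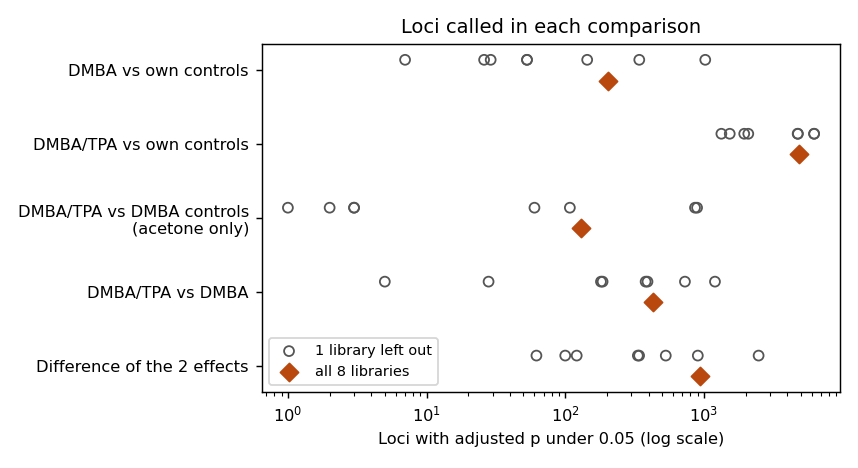
Number of loci with an adjusted p below 0.05 (x axis, log scale) in each of 5 comparisons (y axis). Diamonds are counts from all 8 libraries and open circles counts with 1 library left out; DMBA/TPA has 4886 calls with a range of 1337 to 6239, and DMBA has 204 with a range of 7 to 1023.

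A few loci held a larger share of the counts in each treated library than in any acetone library. The 10 most abundant loci held 21.5% ± 0.639 of the counts in the DMBA controls, 16.9% ± 0.527 in the DMBA/TPA controls, 27.8% ± 2.79 after DMBA and 38.7% ± 3.48 after DMBA/TPA (SD, n = 2 each). All 4 treated libraries lay above all 4 acetone libraries (exact two-sided permutation test within the 2 treatment sets, p = 0.0556, the smallest its 36 splits allow), which does not pass 0.05, and the 4 acetone libraries came from 2 GEO samples. The most abundant locus alone held 5.56% and 4.06% of the counts in the DMBA and DMBA/TPA controls, 8.42% after DMBA and 16.4% after DMBA/TPA. Its log2 fold change was 2.50 with a standard error of 0.258 in DMBA/TPA (edgeR adjusted p = 0.000781) and 0.78 in DMBA (edgeR adjusted p = 0.151). Of the 20 most abundant loci 7 rose and 3 fell after DMBA/TPA. In all 4 settings, the edgeR scalings and DESeq2, 6 and 3 were called in those directions. The share held by Ensembl-format loci went the other way, at 3.87% ± 0.251 and 4.03% ± 0.167 in the DMBA and DMBA/TPA controls, 3.46% ± 0.179 after DMBA and 2.84% ± 0.174 after DMBA/TPA (SD, n = 2 each; exact two-sided permutation test within the 2 sets, p = 0.0556). The 3 shares and the total count were compared in this way, and after Benjamini-Hochberg adjustment over these 4 each had p = 0.0556 in the exact permutation test. The 10 most abundant loci were all assembled loci and included the most abundant one. A larger share for them leaves less for the Ensembl-format loci, so the 3 shares are not separate results. The share of the 10 most abundant loci did not follow the total count throughout: it was 25.8% in the second DMBA library, with 35238753 counts, and 36.2% in the first DMBA/TPA library, with 34537133.

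The acetone controls of the 2 treatments also differed from each other. Relative to the DMBA controls, 131 loci were called in the DMBA/TPA controls, 104 higher and 27 lower, with a median absolute log2 difference of 1.72. MSTRG.14369 had the smallest adjusted p, with a log2 difference of -5.41 and a standard error of 0.338 (edgeR adjusted p = 0.000569). This count was 918 with DESeq2 and 433 with no low-count filter. It was 1 without the first DMBA control library, 2 or 60 without the first or the second DMBA/TPA control library, 893 or 863 without the first or the second DMBA library, and 3 without either DMBA/TPA library. The higher majority turned without the first DMBA library, with 432 higher and 461 lower, and without the second, with 392 higher and 471 lower.

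The treated groups were compared directly as well, although treatment and day of harvest differed together. Relative to DMBA, 433 loci were called in DMBA/TPA, 209 higher and 224 lower, with a median absolute log2 difference of 1.40. MSTRG.2456 was lower in DMBA/TPA, at 134.1 ± 33.3 CPM against 709.6 ± 215 CPM (SD, n = 2 each), a log2 difference of -2.40 with a standard error of 0.266 (edgeR adjusted p = 0.00814). ENSHGLG00000009109 was higher in DMBA/TPA, with a log2 difference of 1.11 and a standard error of 0.182 (edgeR adjusted p = 0.0209). The first of these calls was lost without the second DMBA/TPA library, and the second without any 1 of the DMBA/TPA or DMBA/TPA control libraries or with only these groups in the fit (highest edgeR adjusted p of their 17 alternatives each 0.096 and 0.185). With total counts as the only scaling 14.8% of the called loci were higher, against 48.3% with TMM. The count was 1347 with DESeq2, 728 with no low-count filter, 123 with only these 2 groups in the fit, 181 or 186 without the first or the second DMBA/TPA control library, 1202 or 730 without the first or the second DMBA library, and 28 or 5 without the first or the second DMBA/TPA library. Without the second DMBA library 424 were higher and 306 lower.

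Many loci that rose after DMBA were also higher after DMBA/TPA. Of the 154 loci that rose after DMBA, 87 rose after DMBA/TPA, where independent lists would share 22.3 (Fisher's exact test across loci, p = 5.07e-34). Another 21 fell after DMBA/TPA, where 18.5 would be shared (Fisher's exact test, p = 0.534), and 46 were not called. The number of loci that rose after DMBA and fell after DMBA/TPA depended on single libraries. With 1 library left out it lay above the count expected of independent lists in some fits and below it in others. It was 101 against 86.9 with DESeq2, 43 against 29.8 with no low-count filter, 1 against 16.0 with pooled controls and 7 against 40.8 with the control sets exchanged. Of the 50 loci that fell after DMBA, 17 fell after DMBA/TPA against 6.02 for independent lists (Fisher's exact test, p = 4.31e-05), 3 rose against 7.24 (Fisher's exact test, p = 0.106) and 30 were not called. The 2 comparisons used separate controls but shared 1 fit, with the same estimate of spread for each locus. The share called was larger above 6 than under 0 log2 CPM, at 1.57% against 0.258% in DMBA and 37.4% against 4.29% in DMBA/TPA. Lists of unrelated effects could therefore share more loci than the independent counts given here. Loci are also not independent units for Fisher's exact test. Across all loci the Pearson correlation of the 2 sets of log2 fold changes was 0.11, and the covariance 0.20. Loci called in the same direction in both comparisons numbered 104, against 28.3 for independent lists. The number was 446 against 145 expected with DESeq2 and 227 against 50.6 with no low-count filter. It was 9 against 3.17 with only the groups of each comparison in the fit and 452 against 73.6 with the control sets exchanged. It was 0 with the control columns summed, where DMBA had no calls. With 1 library left out it changed widely but stayed above the expected count each time.

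MSTRG.2456 was among the loci that rose in both, with a log2 fold change of 2.44 and a standard error of 0.269 in DMBA/TPA (edgeR adjusted p = 0.000889). The loci that rose after DMBA had a median log2 fold change of 1.48 in DMBA and 1.00 in DMBA/TPA, and 39 of the 154 were called lower in DMBA/TPA than in DMBA while 4 were called higher. For the loci that fell after DMBA the medians were -1.58 and -0.54, and 14 of the 50 were called higher in DMBA/TPA than in DMBA. These loci were chosen by their DMBA effect, which by itself makes that effect the larger of the 2.

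The difference between the 2 effects was tested for each locus. It was called for 944 loci, with 382 having the higher effect in DMBA/TPA and 562 the lower. ENSHGLG00000009109 fell less in DMBA/TPA than in DMBA, with a difference of 1.30 on the log2 scale (standard error 0.254, edgeR adjusted p = 0.0238). Its own effect in DMBA/TPA was -0.53 (edgeR adjusted p = 0.0536). That effect was negative in all 19 alternatives and passed the threshold in 13 of them, DESeq2 among these (DESeq2 adjusted p = 0.0343). MSTRG.2456 rose less in DMBA/TPA, with a difference of -1.58 (standard error 0.363, edgeR adjusted p = 0.0401). The first of these calls was lost without the second DMBA control library or any 1 of the DMBA/TPA and DMBA/TPA control libraries and with the control sets exchanged, and the second without any 1 control or DMBA/TPA library (highest edgeR adjusted p of their 17 alternatives each 0.178 and 0.177). With the control sets exchanged 34 differences were called, 18 of them among the 944. The count was 1811 with DESeq2, 341, 100, 334, 121 and 62 without the first DMBA control library, the first and the second DMBA/TPA control library and the first and the second DMBA/TPA library, 531 without the second DMBA control library, and 2481 without the first DMBA library. The lower majority turned without the first DMBA library, with 1264 higher and 1217 lower, and without the second, with 471 higher and 433 lower. With upper-quartile scaling 29.0% and with total counts 14.1% of the called differences were higher, against 40.5% with TMM.

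**Figure D3:**
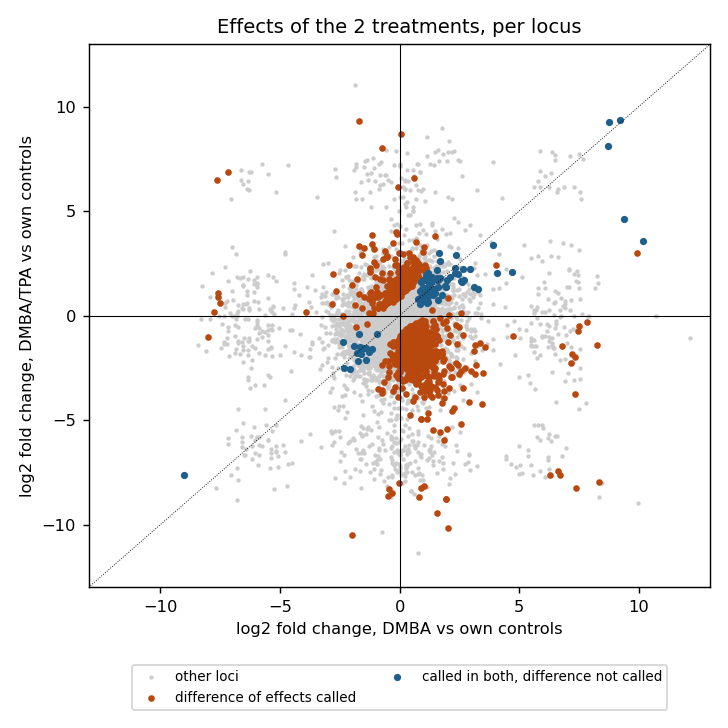
Log2 fold change of each of 18422 loci in DMBA (x axis) and in DMBA/TPA (y axis), each against its own acetone controls. The dotted line marks equal effects; red points are the 944 loci whose effects were called different, and blue points are loci called in both comparisons with no called difference. Fitted values of loci with no counts in a group depend on the model's prior count and are no bounds on the change.

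**Figure D4:**
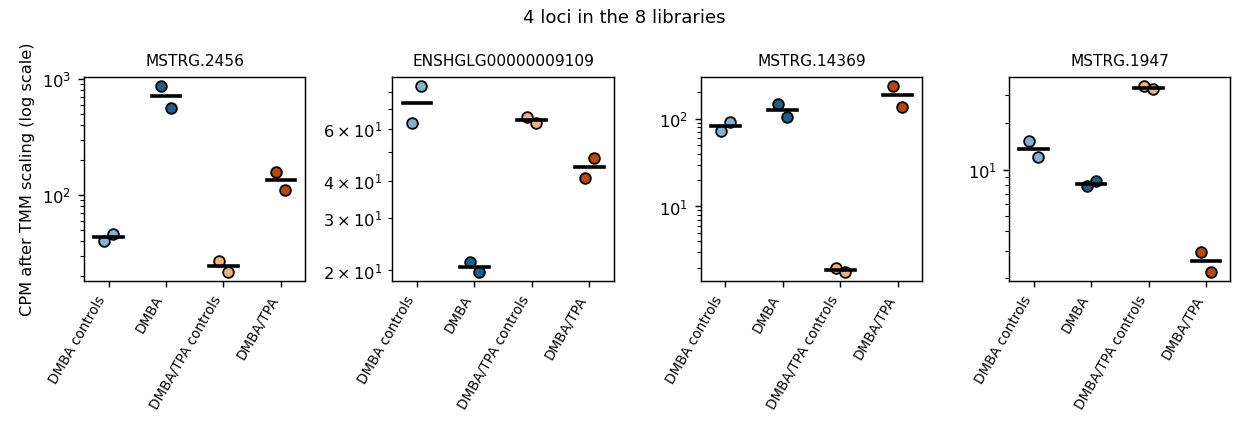
CPM after TMM scaling (y axis, log scale, a separate range per panel) of 4 loci in the 8 libraries by group, with points for libraries and bars for means of 2. MSTRG.14369 is near 1.91 CPM only in the DMBA/TPA controls, and MSTRG.2456 is highest in the DMBA libraries.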

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

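The test of whether the shift between libraries of a group exceeds that of matched lists was chosen only after the result was seen, and the exchange of control sets was chosen after the data were examined.

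The effects of the 2 treatments differed at 944 loci by the test of the difference itself. Of these, 506 had a positive log2 fold change in DMBA and a negative one in DMBA/TPA, with medians of 0.78 and -1.63. These are signs of fitted values: 44 of the 506 were called in DMBA, 443 in DMBA/TPA and 21 in both, and independent lists of calls would share 18.5 in these opposite directions (Fisher's exact test across loci, p = 0.534). Opposite calls of this kind were 101 against 86.9 expected with DESeq2, 1 against 16 with pooled controls and 7 against 40.8 with the control sets exchanged. With 1 library left out they lay above the expected count in some fits and below it in others. The reverse, negative in DMBA and positive in DMBA/TPA, held for 168 loci with medians of -0.35 and 1.26. The difference of effects was -1.58 on the log2 scale for MSTRG.2456, 1.30 for ENSHGLG00000009109, 5.97 for MSTRG.14369 and -2.95 for MSTRG.1947. With the control sets exchanged these were -3.23, 0.92, -4.85 and -0.36, and 34 differences were called.

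The 506 loci with a positive sign in DMBA and a negative one in DMBA/TPA were also higher in the DMBA/TPA controls than in the DMBA controls, by a median of 1.20 on the log2 scale, with 92 of the 131 loci called between controls among them. Between the treated groups the same loci had a median log2 difference, DMBA/TPA against DMBA, of -1.18, with 140 of them called there. Selection by the difference of effects itself favours loci that are high in the DMBA/TPA controls and in DMBA. It also favours those low in the DMBA controls and in DMBA/TPA. These values are therefore no independent evidence on the controls or on the treated groups. With the control sets exchanged, both treatment comparisons together called 68.8% as many loci as with the labelled controls, between the bounds of 50% and 80% set beforehand. The sum hides opposite moves, since DMBA calls went from 204 to 1046 and DMBA/TPA calls from 4886 to 2454. A swap of the control sets and their labelled order cannot be told apart by this test. A component that varies between libraries of 1 group, whatever the treatment, stays open: the mean absolute shift of these loci between the 2 libraries of a group was 0.23, above 100% of 10000 lists matched on abundance, whose highest value was 0.0487, and the 168 loci of the reverse pattern, at 0.076, lay above 99.95% of lists matched to them, shifting the opposite way in all 4 groups. A single component acting on both lists would give this, but so would any lists of loci that vary together, and random lists do not tell these apart. Treatment, day of harvest and the unknown day of the controls stay open as well, and the biological explanation by treatment was not tested apart from them.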

How the results depend on the processing

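Total-count scaling, removal of the 20 most abundant loci, thinning, exchanged control sets and, for the difference of effects, pooled control sets were chosen after seeing the data. Over all alternatives and comparisons, the 4 shown loci gave 352 values, of which 18 passed the threshold newly, 34 no longer passed it, 2 changed direction and the rest kept direction and side. The 2 were the difference of effects of MSTRG.14369, which went from 5.97 to -4.85 with exchanged controls, and the uncalled control difference of ENSHGLG00000009109, which ranged from -0.38 to 0.0282 with 1 library left out. In the treatment comparisons no shown locus changed direction, and 4 calls were lost: ENSHGLG00000009109 in DMBA with only its own groups in the fit, MSTRG.14369 in DMBA/TPA with pooled controls, and MSTRG.2456 and ENSHGLG00000009109 in DMBA with summed control columns. Of the 18 new passes, 13 were of ENSHGLG00000009109 in DMBA/TPA, out of its 19 alternatives there. The log2 fold change in DMBA ranged from 3.68 to 4.85 for MSTRG.2456 and -2.02 to -1.61 for ENSHGLG00000009109. In DMBA/TPA it ranged from 1.18 to 6.93 for MSTRG.14369 and -4.18 to -2.41 for MSTRG.1947. The counts of calls moved far more, and the cause was not tested. With DESeq2 they were 946 in DMBA, 1811 for the difference of effects, 918 between controls, 1347 between treated groups and 446 shared in direction. With no low-count filter they were 469 in DMBA, 433 between controls, 728 between treated groups and 227 shared. With only the compared groups in the fit they were 16 in DMBA, 7338 in DMBA/TPA, 123 between treated groups and 9 shared. With pooled controls 189 loci were shared, where simulated groups without effect gave 0 and independent lists 28.3. Groups without effect yield almost no calls, so the 0 does not measure what shared controls add, and the 28.3 leaves them out. The covariance of effects was 0.58 against 0.10 simulated, from 20 simulations, and the correlation 0.43 against 0.31. With the controls split into their own sets, 104 loci were shared, the covariance was 0.20 and the correlation 0.11. With summed control columns the counts were 0 in DMBA (edgeR, 1786 at an unadjusted p below 0.05), 891 in DMBA/TPA and 0 shared. With exchanged controls they were 1046 in DMBA, 2454 in DMBA/TPA, 34 for the difference of effects and 452 shared. With pooled controls the controls cancel from the difference of effects, leaving the contrast of the treated groups, with 77 calls. The fit of 4 groups gave 433 calls for that same contrast, so there the fitted spread changed and the contrast did not. Against the 944 called differences of effects, both the contrast and the spread changed. Total-count scaling gave 764 between treated groups, and a threshold of 0.1 gave 300 shared.

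With 1 library left out, the counts ranged from 7 to 1023 in DMBA, 1337 to 6239 in DMBA/TPA, 62 to 2481 for the difference of effects, 1 to 893 between controls, 5 to 1202 between treated groups and 6 to 694 shared. The replicate block over the treated groups gave 371 calls against 433; deviations of same-numbered samples correlated at -0.000106, so the numbers were not taken as pairs. Thinning to the smallest total gave 209 calls in DMBA and 4835 in DMBA/TPA, so depth beyond 22852358 counts added little. Alternatives for gene lists were not run, since no list could be matched.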

Other observations

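The explanation by wider spread was added after the counts with 1 library left out had been seen, though before its variances were. The ranges with 1 library left out that accompany each test were chosen only after the tests' main results were seen.

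The DMBA/TPA comparison called 24.0 times as many loci as the DMBA comparison, a ratio that lay between 6.10 and 678 with 1 library left out and was 5.87 with DESeq2 (5557 against 946) and 2.35 with the control sets exchanged. The tables argue against a difference in depth. After thinning every library to the smallest total the ratio was 23.1 (5.53 to 679 with 1 library left out). Without the 20 most abundant loci it was 24.1 (5.95 to 679), and with total counts alone, which leave the weight of such loci in, 43.6. TMM scaling already limits that weight, so the removal could hardly move the ratio. It does not decide how far a few loci taking most of the counts add to the excess of DMBA/TPA calls. The DMBA/TPA controls standing apart may account for part of it: 2454 loci were called in DMBA/TPA against the DMBA controls, 12.0 times the DMBA count, but that ratio fell below the bound of 5 set beforehand, to 3.03, without the second DMBA/TPA library, and with the DMBA/TPA controls for both treatments it was 4.67 and fell to 1.87 without the second DMBA library. Wider spread between the DMBA libraries stays open too, because the variance of log2 fold changes left after subtracting that between libraries was 3.48 times as large in DMBA/TPA, above the bound of 3 set beforehand, but 1.86 times without the second DMBA control library and 4.92 times without the first. The mean variance of log2 CPM between the 2 libraries of a group was 0.403 in the DMBA controls and 0.385 in DMBA. In the DMBA/TPA controls it was 0.291 and in DMBA/TPA 0.304, so the spread was wider in both groups of the DMBA comparison. With only the compared groups in each fit, the ratio of calls was 459 (7338 against 16). The variance left was 0.90 in DMBA/TPA, 0.26 in DMBA, 0.27 between controls and 0.35 between treated groups. Treatment with its day of harvest remains as an open biological explanation.

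Assembled loci with consecutive numbers were called together more often than shuffled ones. In DMBA/TPA 736 of 11787 consecutive pairs were called in the same direction, against a mean of 531.3 and a maximum of 592 over 1000 shuffles (permutation p = 0.001, the smallest they can give), and 411 were called in opposite directions, against a mean of 523.1. For the difference of effects 75 pairs were called in the same direction, against a mean of 20.3. A candidate explanation is that such loci are pieces of 1 gene, or neighbours that move together whatever the treatment. Among 5778 pairs with neither locus called in a treatment comparison, the median correlation of deviations from group means was 0.143. Random pairs of such loci had 0.0043. The 736 pairs called in the same direction in DMBA/TPA had 0.34, but the bounds were set for uncalled pairs and do not judge that value. The 0.143 lay between the bounds of 0.1 and 0.3 set beforehand, so the test leaves this joint explanation undecided. It does not separate pieces of 1 gene from neighbours, for which positions would be needed, and these were not used here.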
